A study of Mus musculus with 6 samples.

How the data were processed

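Gene expression was measured by RNA sequencing in mouse neural stem and progenitor cell cultures, in 6 libraries of 3 groups: control, PQ and NAC, 2 libraries each, all at 48 h per the labels. Total RNA was extracted with TRIZOL, and the protocol names rRNA depletion or oligo dT selection, without saying which was applied, N6 random primers and the BGISEQ-500 sequencer, per the labels' protocols. The library numbers in the titles are 8 and 11 for control, 9 and 12 for PQ and 10 and 13 for NAC, and the labels do not say whether runs of consecutive numbers are batches. The replicate numbers used here follow the order of the samples and mark no pairing.

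The deposited tables hold 1 line per gene with a gene identifier, transcripts, a length, an expected count and an FPKM value, per the file headers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM and the mm10 genome, without giving the role of each tool. The deposited expected counts are estimates, and 20.9% to 21.4% of their values in a library are not whole numbers. FPKM values were deposited beside them, per the file headers, and were used only in alternatives. Each table lists only genes above 0, so a gene absent from a table was set to 0. Of 17254 gene identifiers 17199 carried a name in the annotation table, and the other 55 held 0.072% to 0.079% of the counts of a library. The list of 26 mitochondrially encoded genes had 0 tested members and is not analysed here. The sources used here do not say whether counting used the strand, so a gene that shares exons with a gene on the other strand can hold reads of both. Of 215 named genes 214 were found by name in the annotation (not Ero1a), and 15 share exonic bases with another tested gene, all on the opposite strand. They are Ctsb, Emx2, Fosl1 (62.4% of its bases), Igsf10, Lamp1, Lhfpl3, Map1lc3b, Mest, Nefl, Nefm, Nkx2-2, Pfkp, Prdx5, Sqstm1 and Txnip.

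Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12813 genes, and libraries were scaled by TMM. A quasi-likelihood fit with 1 mean per group over all 6 libraries, with 3 residual degrees of freedom, was tested for PQ against control, NAC against control and PQ against NAC. Its p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05, and adjusted p for genes is edgeR's throughout. Folds and log2 fold changes come from that fit, and levels are CPM, counts scaled to library size with TMM factors, as mean and SD of 2 libraries. Errors of log2 fold changes are approximate standard errors (SE). Each is the absolute log2 fold change divided by the square root of the F statistic of its quasi-likelihood test. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

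Summed expected counts were 9680436 to 10698241 per library. On simulated data with the depth and spread of these libraries, in which 200 genes were changed and 12672 passed the filter, the test found 63.64% of genes changed 1.5-fold, 89.39% of those changed 2-fold and 93.94% of those changed 4-fold in PQ against control, with a false share of 5.23%. In PQ against NAC it found 62.12%, 87.88% and 96.97%. A gene that did not pass can therefore have changed by 1.5-fold.

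Before the data were examined, 27 gene lists were written from general knowledge. Stress and metabolism lists were NRF2 targets, antioxidant enzymes, metallothioneins and metal handling, p53 targets, amino acid response (ATF4), endoplasmic reticulum chaperones, heat shock proteins, hypoxia and glycolysis, nuclear respiratory chain, mitochondrially encoded genes and cholesterol synthesis. Cycle and cell type lists were S phase, G2 and M phase, neural stem cell and radial glia, neurogenic and neuronal, astrocyte, oligodendrocyte lineage, microglia and blood cell, endothelial, fibroblast and pericyte. The others were Notch pathway, immediate early, interferon-stimulated, inflammatory (NF-kB), sirtuins and NAD metabolism, cytosolic ribosomal proteins, and lysosome and autophagy. The 24 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists of a comparison. Cell type lists describe bulk cultures and count no cells. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list only.

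The genes named were set by a rule: in each comparison the 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups. It added up to 4 members of each list with the smallest p, and a panel of 18 genes. Loci without a gene name that the rule picked are not printed, and Dcx of the panel was below the filter. Where 5 or fewer members of a list moved in a direction they were to be named as well, but some genes that this or the rule picked are not reported here, so fewer can be named than counted. Those outside the rule were chosen after their values were seen, as were the near-copies of named genes. The tests of explanations in the closing section and the list of imprinted genes were also chosen after the data were seen.

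Each gene result was recomputed under 16 alternatives: DESeq2 1.42.0, RLE scaling, library size only, no filter, a mean of at least 5 CPM, and others. These were limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes at FPKM of 1 or more in at least 2 libraries, only the 2 groups compared, a robust fit, a block by run of library numbers, and each of the 6 libraries left out. Lists had 12 alternatives, among them a correlation estimated from the residuals and the fry test, and the correlation between treatments had 11. Where 1 library of a group is left out, the lone library is assumed to vary like the other groups.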

Results

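RNA was sequenced from cultured mouse neural stem and progenitor cells, which were kept in N2 medium with the growth factors EGF and bFGF. The series text gives the aim as setting intracellular redox potential to different levels over 48 h and measuring the gene expression that followed. The labels name 3 groups of 2 libraries each, a control, cells given PQ and cells given NAC, and they spell out neither abbreviation and give no dose. Nothing says that the 2 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical. The summed expected counts per library were 10040827 and 9849392 for control, 9680436 and 10388731 for PQ, and 10698241 and 9907726 for NAC. After filtering 12813 genes were tested. Libraries of 1 group differed by more than counting noise (chi-square per degree of freedom 6.91 for control, 4.11 for PQ and 4.75 for NAC), and pairs from different groups differed more (14.95 to 37.81). The first principal component of log2 CPM (counts scaled to library size) held 48.8% of the variance and placed control (-5.73 and -4.29) between PQ (-27.09 and -27.13) and NAC (34.49 and 29.75). The second held 26.2% and set control (22.14 and 27.52) apart from both treatments (-7.48 to -18.75).

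**Figure D1:**
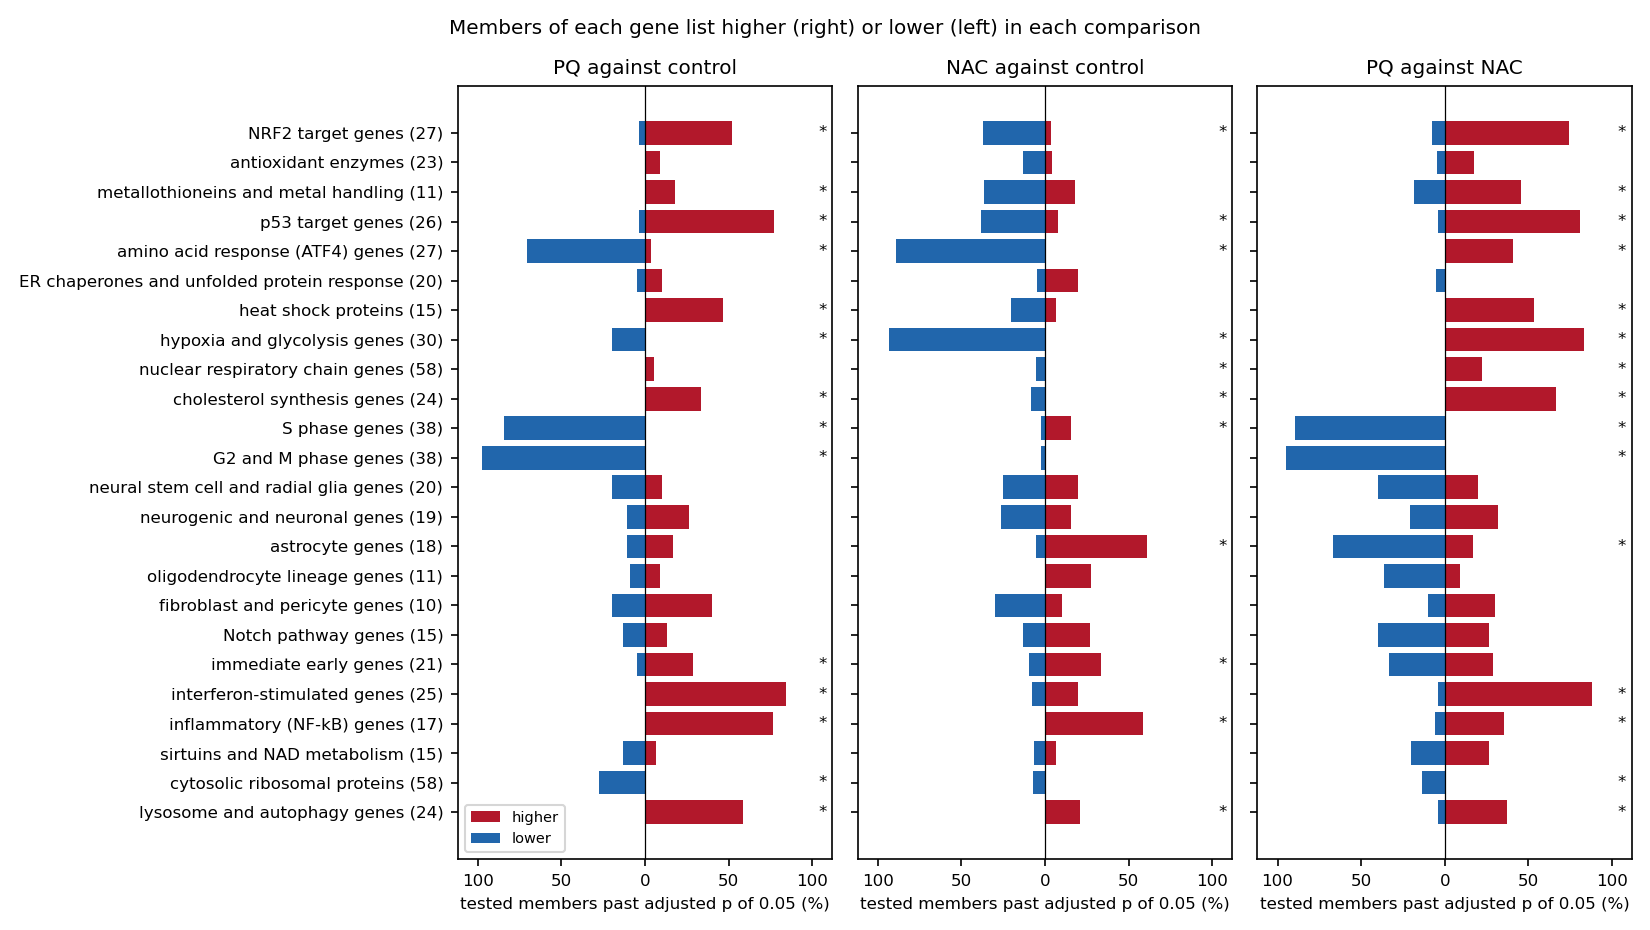
Share of the tested members of 24 gene lists that were higher (red, right) or lower (blue, left) at an edgeR adjusted p under 0.05, in percent. Brackets give the number of tested members, and a star marks lists that passed camera with its preset correlation.

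The first comparison, PQ against control, asks what differed after 48 h with PQ. Most listed genes of the cell division cycle fell, most p53 targets, interferon-stimulated and inflammatory genes and 14 of 27 NRF2 targets rose, and most genes of the amino acid response driven by ATF4 fell. Mki67, whose protein Ki-67 marks dividing cells, went from 1068 ± 19.4 to 485 ± 49.7 CPM (SD, n = 2), a 2.2-fold decrease. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, went from 470.4 ± 4.11 to 1058 ± 37.2 CPM, a 2.25-fold increase. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 2289 of the 12813 genes, 1162 higher and 1127 lower with PQ, of which 204 and 87 changed by at least 2-fold. With library size as the only scaling the split was 1332 higher and 965 lower. The call count fell to 846 without PQ replicate 2 and to 1487 without PQ replicate 1. Of the 24 lists tested as sets, 14 passed camera with its preset correlation, 0 passed with an estimated correlation (4 had an unadjusted p under 0.05), and 11 passed fry. Those called by camera that did not pass fry were the metallothionein, amino acid response, hypoxia, cholesterol synthesis and immediate early lists. Because 0 passed with an estimated correlation, that adjusted p is given beside each list camera called.

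With PQ, 37 of 38 tested G2 and M phase genes fell and 0 rose (38 fell adjusted over the list alone, camera adjusted p = 1.6e-31, adjusted p = 0.19 with an estimated correlation). They included Racgap1 and Aurkb, which act in cytokinesis and chromosome segregation, with log2 fold changes of -0.94 ± 0.09 and -0.97 ± 0.10 (SE). Of 38 S phase genes 32 fell and 0 rose (33 fell adjusted over the list alone, camera adjusted p = 2.4e-25, adjusted p = 0.19 with an estimated correlation). The replicative helicase subunits Mcm5, Mcm6 and Mcm2 fell 1.9-fold, 1.87-fold and 1.82-fold, with edgeR adjusted p up to 9.6e-06. Among 26 p53 targets 20 rose and 1 fell (20 and 2 adjusted over the list alone, camera adjusted p = 1.6e-15, adjusted p = 0.093 with an estimated correlation). Eda2r, a receptor of the TNF receptor family, and the p53-induced genes Ccng1 and Trp53inp1 rose 2.48-fold, 2.5-fold and 2.47-fold, each with an edgeR adjusted p of 3.4e-07 or less. The member that fell was Sesn2 (-0.50 ± 0.15), a stress gene that ATF4 also induces. Its edgeR adjusted p of 0.03 became 0.41 without control replicate 2, 0.17 without PQ replicate 1 and 0.089 without PQ replicate 2. Cdkn1a (Entrez gene 12575) lies on chromosome 17 from 29090979 to 29100722 of the GRCm38 assembly.

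Interferon-stimulated genes rose in 21 of 25 members with PQ and fell in 0 (21 and 0 adjusted over the list alone, camera adjusted p = 3.1e-18, adjusted p = 0.19 with an estimated correlation), and 13 rose when PQ replicate 2 was left out. Rsad2, Ifit1 and Ifit3, antiviral effectors, reached 4.48-fold, 4.05-fold and 4.51-fold of control, and the guanylate-binding proteins Gbp2 and Gbp10 3.5-fold and 3.5-fold. Ifit3b, a near-copy of Ifit3, had a log2 fold change of 2.01 ± 0.27 that ranged from 1.52 without control replicate 1 to 2.74 without control replicate 2, and summed with Ifit3 it was 2.09. Reads of Gbp2 with Gbp2b, and of Gbp10 with Gbp6, may also be shared between copies, and their sums were higher by 1.78 and 1.66 on the log2 scale. Of 17 inflammatory genes 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 6.3e-13, adjusted p = 0.19 with an estimated correlation). The chemokines Cxcl10 and Ccl2, the iron-scavenging lipocalin Lcn2 and the cytokine Lif rose 2.77-fold, 2.93-fold, 2.38-fold and 2.49-fold (edgeR adjusted p at most 5.7e-06). Tlr2, an innate immune receptor, and Ass1, the argininosuccinate synthase of arginine synthesis, were low in control (2.25 ± 0.101 and 1.64 ± 0.113 CPM) and rose to 9.06 ± 2.51 and 8.37 ± 0.939 CPM. Of the 20 microglia and blood cell genes 4 could be tested, and 1 rose and 0 fell (2 and 0 adjusted over the list alone), with a higher estimate for all 4 (median log2 fold change 0.51). Without any 1 control or PQ library 0 rose.

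Amino acid response genes fell in 19 of 27 members with PQ and 1 rose (23 and 1 adjusted over the list alone, camera adjusted p = 5.5e-18, adjusted p = 0.26 with an estimated correlation). Chac1, which degrades glutathione, fell 5.8-fold, from 43.6 ± 15.8 to 7.49 ± 0.433 CPM. The amino acid transporters Slc7a5 and Slc7a1 fell 4.27-fold and 2.96-fold, and the mitochondrial one-carbon enzymes Mthfd2 and Shmt2 3.1-fold and 2.71-fold. Pck2, which makes phosphoenolpyruvate in mitochondria, and Bcat1, which transaminates branched-chain amino acids, were 3.42-fold and 3.14-fold lower (edgeR adjusted p 2e-06 and 0.00012). Control replicate 2 was higher than control replicate 1 for several of them: the log2 fold change of the pseudokinase gene Trib3, -2.06 ± 0.24, was -1.45 without it, and that of Ddit3, a transcription factor of the stress response, went from -1.03 ± 0.23 to -0.34. The edgeR adjusted p of Ddit3 was 0.16 without control replicate 2 and 0.051 without PQ replicate 2. The member that rose was Cebpb (0.75 ± 0.21), with an edgeR adjusted p of 0.22 without PQ replicate 2 and 0.13 without control replicate 1. Txnip, which binds and inhibits thioredoxin, was the named gene with the largest decrease, from 16.1 ± 4.44 to 2.19 ± 0.14 CPM (7.31-fold, edgeR adjusted p = 7.2e-07), and 21.4% of its exonic bases overlap a gene on the other strand.

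NRF2 targets rose in 14 of 27 members with PQ and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 9.9e-08, adjusted p = 0.19 with an estimated correlation), with 8 rising without control replicate 2 and 7 without PQ replicate 2. Hmox1, which encodes heme oxygenase 1, rose from 64.1 ± 3.17 to 129.7 ± 18.5 CPM (log2 fold change 1.02 ± 0.11), and the ferritin heavy chain Fth1, the autophagy adaptor Sqstm1 and the sulfiredoxin Srxn1 rose 1.72-fold, 1.76-fold and 1.66-fold. The one that fell was the pentose phosphate enzyme Tkt (-0.30 ± 0.09), with an edgeR adjusted p of 0.18 without PQ replicate 2, 0.13 without PQ replicate 1 and 0.11 without control replicate 1. Txnrd1, a thioredoxin reductase, rose 1.27-fold, with an edgeR adjusted p of 0.13 without PQ replicate 2. Nqo1 (0.93 ± 0.33, edgeR adjusted p = 0.058), the glutamate cysteine ligase subunit Gclm (0.23 ± 0.10, 0.14) and the cystine transporter Slc7a11 (-0.12 ± 0.09, 0.4) did not pass. Among 23 antioxidant enzymes 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.54). They were the extracellular superoxide dismutase Sod3 (0.91 ± 0.15) and the glutathione peroxidase Gpx1 (0.37 ± 0.10), the latter with an edgeR adjusted p of 0.15 without PQ replicate 2. Of 11 metallothionein and metal handling genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.34 with an estimated correlation). Mt3 (0.80 ± 0.10) and the transferrin receptor gene Tfrc (0.77 ± 0.11) were the 2. The list call was lost without control replicate 2 (adjusted p = 0.11) and without PQ replicate 1 (0.12). Heat shock proteins rose in 7 of 15 members and fell in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00092, adjusted p = 0.22 with an estimated correlation). Without PQ replicate 2 the number that rose was 4. Hspb8 and Cryab, small heat shock proteins, rose 1.95-fold and 1.72-fold.

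Hypoxia and glycolysis genes fell in 6 of 30 members with PQ and rose in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.59 with an estimated correlation). The list call was lost without control replicate 1 and without PQ replicate 2 (adjusted p up to 0.22), where 3 and 1 members fell. The hexokinase gene Hk2 fell 1.52-fold, and Egln1 (-0.43 ± 0.11), which senses oxygen, and Vegfa (-0.41 ± 0.11), which encodes an angiogenic factor, fell. Their edgeR adjusted p was 0.24 without PQ replicate 2 for Egln1 and 0.22 without PQ replicate 2 for Vegfa. Neural stem cell and radial glia genes fell in 4 and rose in 2 of 20 members (5 and 4 adjusted over the list alone, camera adjusted p = 0.22). Those that fell were Nr2e1 (-0.67 ± 0.13), a nuclear receptor of neural stem cells, the glutamate transporter Slc1a3 (-0.48 ± 0.09), Sox2 (-0.36 ± 0.10) and Ptprz1 (-0.30 ± 0.09). Those that rose were Tnc (0.40 ± 0.09) and the intermediate filament gene Nes (0.34 ± 0.09). Neurogenic and neuronal genes rose in 5 and fell in 2 of 19 members (5 and 3 adjusted over the list alone, camera adjusted p = 0.9). The neuronal tubulin Tubb3, at 3.29 ± 1.37 CPM in control, was 3.13-fold lower. Celf4 (0.77 ± 0.14), Nefl (0.55 ± 0.14), Nefm (0.51 ± 0.13), Eomes (1.00 ± 0.33) and Gad1 (0.93 ± 0.31) rose, and Nefl and Nefm share exonic bases on opposite strands. Of 18 astrocyte genes 3 rose, Apoe (2.46-fold), Aldh1l1 (1.17 ± 0.26) and Gja1 (0.31 ± 0.09), and 2 fell, Fgfr3 (-1.01 ± 0.12) and Slc4a4 (-0.83 ± 0.12) (6 and 2 adjusted over the list alone, camera adjusted p = 0.2). Gfap (-0.06 ± 0.24, edgeR adjusted p = 0.91), Hes1 (-0.25 ± 0.11, 0.14), Olig2 (-0.20 ± 0.09, 0.15) and Sirt1 (-0.16 ± 0.15, 0.51) did not pass, and the Gfap value was 0.15 without control replicate 1 and 0.04 without PQ replicate 2. Leaving out 1 library ended some of these calls, with the edgeR adjusted p as follows. Sox2 was at 0.16 without control replicate 2, 0.13 without PQ replicate 2 and 0.074 without PQ replicate 1. Ptprz1 was at 0.16 without PQ replicate 2, 0.12 without PQ replicate 1 and 0.1 without control replicate 2. Nes was at 0.091 without PQ replicate 2, 0.059 without PQ replicate 1 and 0.054 without control replicate 2. Tubb3 was at 0.15 without control replicate 2 and 0.087 without PQ replicate 1. Nefl was at 0.06 without PQ replicate 1. Nefm was at 0.066 without PQ replicate 1 and 0.053 without PQ replicate 2. Eomes was at 0.38 without PQ replicate 2, 0.089 without control replicate 1 and 0.071 without control replicate 2. Gad1 was at 0.054 to 0.28 without any 1 of the 6 libraries. Aldh1l1 was at 0.1 without PQ replicate 2. Gja1 was at 0.2 without PQ replicate 1, 0.087 without control replicate 1 and 0.063 without PQ replicate 2.

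NAC against control is the second comparison, with the same question for the other agent. Most hypoxia and glycolysis genes and amino acid response genes fell with NAC, and 11 of 18 astrocyte and 10 of 17 inflammatory genes rose. Ero1a, an endoplasmic reticulum oxidase induced by hypoxia, fell 2.81-fold, from 3052 ± 139 to 1088 ± 81.5 CPM (SD, n = 2), and Chac1 fell 11.8-fold to 3.7 ± 0.511 CPM. Selenop, which encodes the selenium carrier selenoprotein P, rose 4.88-fold, from 50.9 ± 0.415 to 248 ± 22.7 CPM. In edgeR the quasi-likelihood test with Benjamini-Hochberg adjustment called 2294 genes, 1108 higher and 1186 lower with NAC, of which 212 and 237 changed by at least 2-fold. Scaled by library size only, the split was 1392 higher and 986 lower, and without NAC replicate 1 the count was 1332. Of the 24 lists 11 passed camera with its preset correlation, 0 passed with an estimated one (1 had an unadjusted p under 0.05) and 1 passed fry, the astrocyte list.

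With NAC, 28 of 30 hypoxia and glycolysis genes fell and 0 rose (28 and 0 adjusted over the list alone, camera adjusted p = 8.4e-26, adjusted p = 0.46 with an estimated correlation). Among them were the phosphofructokinase Pfkp (2.24-fold), Ndrg1 (2.46-fold) and the glucose transporter Slc2a3 (2.48-fold), with edgeR adjusted p up to 1.5e-06, and P4ha2, a collagen prolyl hydroxylase, fell 3.88-fold. Amino acid response genes fell in 24 of 27 members and rose in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 2.7e-26, adjusted p = 0.46 with an estimated correlation). Asns, the asparagine synthetase, fell 4.51-fold, and Shmt2, the proline synthesis enzyme Aldh18a1 and Bcat1 2.71-fold, 3.01-fold and 5.37-fold. Control replicate 2 raised the size of some decreases: without it the log2 fold changes of Trib3 (-2.84 ± 0.26), Nupr1 (-1.91 ± 0.21) and Ddit3 (-1.31 ± 0.24) were -2.23, -1.28 and -0.61. A robust quasi-likelihood fit ended the calls of Nupr1 and Ddit3 (edgeR adjusted p = 0.076 and 0.15). Adssl1, an enzyme of AMP synthesis, the lipase Lipg and Ripor2 were also among the genes with the largest decreases, by 4.92-fold, 3.99-fold and 5.81-fold. Of 26 p53 targets 10 fell and 2 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.46 with an estimated correlation). Cdkn1a (1.97-fold) and Sesn2 (2.56-fold) fell, and the death receptor gene Fas (0.96 ± 0.17) and Eda2r (0.32 ± 0.10) rose. The edgeR adjusted p of Eda2r was 0.15 without NAC replicate 2, 0.1 without control replicate 1, 0.093 without NAC replicate 1, 0.055 without control replicate 2 and 0.052 without PQ replicate 2.

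Astrocyte genes rose in 11 of 18 members with NAC and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.8e-07, adjusted p = 0.4 with an estimated correlation). The acyl-CoA synthetase Acsbg1, Apoe, the aldolase Aldoc and the sodium pump subunit Atp1b2 rose 2.13-fold, 3.88-fold, 2.12-fold and 2.11-fold, Gfap rose 2.34-fold from 5.27 ± 0.984 CPM, and Gja1 fell (-0.43 ± 0.09), with 2 lower members without control replicate 2. The genes with the largest increases were Cd14, a lipopolysaccharide co-receptor (7.17-fold), Lhfpl3 (7.09-fold), the cadherin Pcdh15 (6.86-fold), the metalloreductase Steap4 (5.21-fold), Tlr2 (4.71-fold) and the complement gene C4b (4.65-fold), with edgeR adjusted p from 1.5e-10 for Selenop to 6e-06 for Tlr2. Inflammatory genes rose in 10 of 17 members and fell in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.46 with an estimated correlation). Lcn2 was at 2.01-fold, the NF-kB inhibitor Nfkbia at 1.71-fold and Ccl2 at 1.85-fold of control. Of 25 interferon-stimulated genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.28). Gbp2 (2.13 ± 0.12), Ifit2 (0.52 ± 0.11), Ifit3 (1.09 ± 0.24) and Rsad2 (0.65 ± 0.16) were among those that rose, with 3 higher without NAC replicate 1, and the class I histocompatibility genes H2-D1 (-0.41 ± 0.11) and H2-K1 (-0.34 ± 0.10) fell. Leaving out 1 library ended 3 of these calls, at these edgeR adjusted p. Rsad2 was at 0.079 without NAC replicate 1. H2-D1 was at 0.23 without NAC replicate 1. H2-K1 was at 0.29 without NAC replicate 1 and 0.12 without control replicate 1. The microglia gene P2ry12, an ADP receptor, was the 1 of 4 tested on its list to rise (1 and 0 adjusted over the list alone), from 3.33 ± 0.427 to 7.52 ± 2.09 CPM (edgeR adjusted p = 0.0034, and 0.09 without NAC replicate 1).

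NRF2 targets fell in 10 of 27 members with NAC and 1 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.46 with an estimated correlation). Without control replicate 1 the camera adjusted p was 0.11, and 6 fell without NAC replicate 1. The glutathione conjugate exporter Abcc1, Tkt and the aldo-keto reductase Akr1b8 fell 1.84-fold, 1.53-fold and 1.94-fold, and Sqstm1 rose (0.46 ± 0.10). Hmox1 (-0.46 ± 0.12) and Srxn1 (-0.46 ± 0.12) fell, at an edgeR adjusted p of 0.14 without NAC replicate 1 for Hmox1 and 0.14 without control replicate 1 and 0.12 without NAC replicate 1 for Srxn1. Nqo1 (0.06 ± 0.36, edgeR adjusted p = 0.93), Gclm (-0.19 ± 0.10, 0.25), Txnrd1 (-0.09 ± 0.09, 0.53) and Slc7a11 (-0.24 ± 0.09, 0.059) did not pass, and Nqo1 was at -0.17 without control replicate 2 and -0.29 without NAC replicate 1. Of 23 antioxidant enzymes 3 fell and 1 rose (3 and 3 adjusted over the list alone, camera adjusted p = 0.58). Gpx1 fell 1.84-fold and the thioredoxin Txn1 rose 1.66-fold. Gpx8 (-0.38 ± 0.13) and Prdx5 (-0.31 ± 0.10) fell, calls that leave-outs ended at these edgeR adjusted p. Gpx8 was at 0.39 without control replicate 2, 0.17 without NAC replicate 2, 0.13 without NAC replicate 1 and 0.052 without PQ replicate 1. Prdx5 was at 0.36 without NAC replicate 1, 0.098 without control replicate 2, 0.072 without control replicate 1, 0.064 without PQ replicate 1 and 0.061 without PQ replicate 2. Metallothionein and metal handling genes fell in 4 and rose in 2 of 11 members (4 and 3 adjusted over the list alone, camera adjusted p = 0.26). The metallothioneins Mt1, Mt2 and Mt3 fell 1.92-fold, 1.95-fold and 1.67-fold and the copper pump Atp7a 1.6-fold. The zinc and iron importers Slc39a10 (0.36 ± 0.10) and Slc11a2 (0.37 ± 0.13) rose, calls that ended in leave-outs at these edgeR adjusted p. Slc39a10 was at 0.14 without NAC replicate 1 and 0.054 without control replicate 2. Slc11a2 was at 0.32 without NAC replicate 2, 0.28 without control replicate 2, 0.066 without PQ replicate 2, 0.061 without PQ replicate 1 and 0.051 without NAC replicate 1. Heat shock proteins fell in 3 of 15 members, Cryab (2.46-fold), Hspb8 (-0.44 ± 0.10) and Hspa4l (-0.33 ± 0.10), and rose in 1, Hspa8 (0.35 ± 0.09) (3 and 1 adjusted over the list alone, camera adjusted p = 0.28). All but Cryab lost their calls without 1 library, with the edgeR adjusted p as follows. Hspb8 was at 0.083 without NAC replicate 1 and 0.057 without control replicate 1. Hspa4l was at 0.15 without NAC replicate 2, 0.088 without NAC replicate 1 and 0.064 without control replicate 1. Hspa8 was at 0.16 without control replicate 2 and 0.12 without NAC replicate 1.

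With NAC few G2 and M phase genes changed, while some S phase genes rose. Of the 38 S phase genes 30 had a higher estimate. In this comparison 17.9% of all tested genes were called. S phase genes rose in 6 of 38 members and 1 fell, E2f1 (-0.63 ± 0.13) (6 and 2 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.57 with an estimated correlation). The list call was lost without control replicate 2 (0.099), and the number that rose was 12 without control replicate 1 and 1 without control replicate 2 or NAC replicate 1. The replicative helicase gene Mcm4 rose (0.48 ± 0.11), at an edgeR adjusted p of 0.064 without NAC replicate 1 and 0.058 without control replicate 2. Of 38 G2 and M phase genes 1 fell, the cytokinesis gene Anln (-0.55 ± 0.10), and 0 rose, with 2 lower without control replicate 1 (1 and 0 adjusted over the list alone, camera adjusted p = 0.78), with a median of 0, a mean of 0.01 and an upward test. Mki67 was at 0.26 ± 0.10 (edgeR adjusted p = 0.074). Neural stem cell and radial glia genes fell in 5 and rose in 4 of 20 members (5 and 5 adjusted over the list alone, camera adjusted p = 0.91, with a median of 0.04 and a downward test). The intermediate filament gene Vim (-0.76 ± 0.09), Tnc (-0.68 ± 0.09), Id1 (-0.49 ± 0.14), Sox2 (-0.31 ± 0.10) and Nes (-0.28 ± 0.09) fell, and Ptprz1 (0.75 ± 0.09), Id3 (0.67 ± 0.13), Emx2 (0.49 ± 0.14) and Slc1a3 (0.29 ± 0.09) rose. Neurogenic and neuronal genes fell in 5 and rose in 3 of 19 (5 and 3 adjusted over the list alone, camera adjusted p = 0.28). The neurofilament genes Nefm and Nefl fell 1.98-fold and 1.98-fold, Celf4 2.23-fold, Insm1 4.6-fold and Tubb3 4.83-fold, to 0.674 ± 0.167 CPM, while Map2 (0.77 ± 0.10), Gap43 (1.23 ± 0.20) and Robo2 (0.38 ± 0.11) rose. Hes1 (0.13 ± 0.11, edgeR adjusted p = 0.47) and Olig2 (0.07 ± 0.09, 0.65) did not pass, and the NAD-dependent deacetylase Sirt1 rose 1.39-fold. Calls ended without 1 library for 7 of these genes, with the edgeR adjusted p as follows. Id1 was at 0.18 without NAC replicate 1, 0.11 without control replicate 2 and 0.058 without NAC replicate 2. Sox2 was at 0.27 without control replicate 2, 0.16 without NAC replicate 1 and 0.085 without NAC replicate 2. Nes was at 0.054 to 0.15 without any 1 of the 6 libraries. Emx2 was at 0.15 without NAC replicate 1 and 0.13 without control replicate 1. Slc1a3 was at 0.25 without control replicate 1, 0.16 without NAC replicate 1, 0.11 without NAC replicate 2, 0.057 without PQ replicate 2 and 0.054 without PQ replicate 1. Robo2 was at 0.12 without control replicate 1, 0.11 without NAC replicate 1 and 0.062 without NAC replicate 2. Sirt1 was at 0.28 without NAC replicate 1 and 0.16 without control replicate 1.

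**Figure D2:**
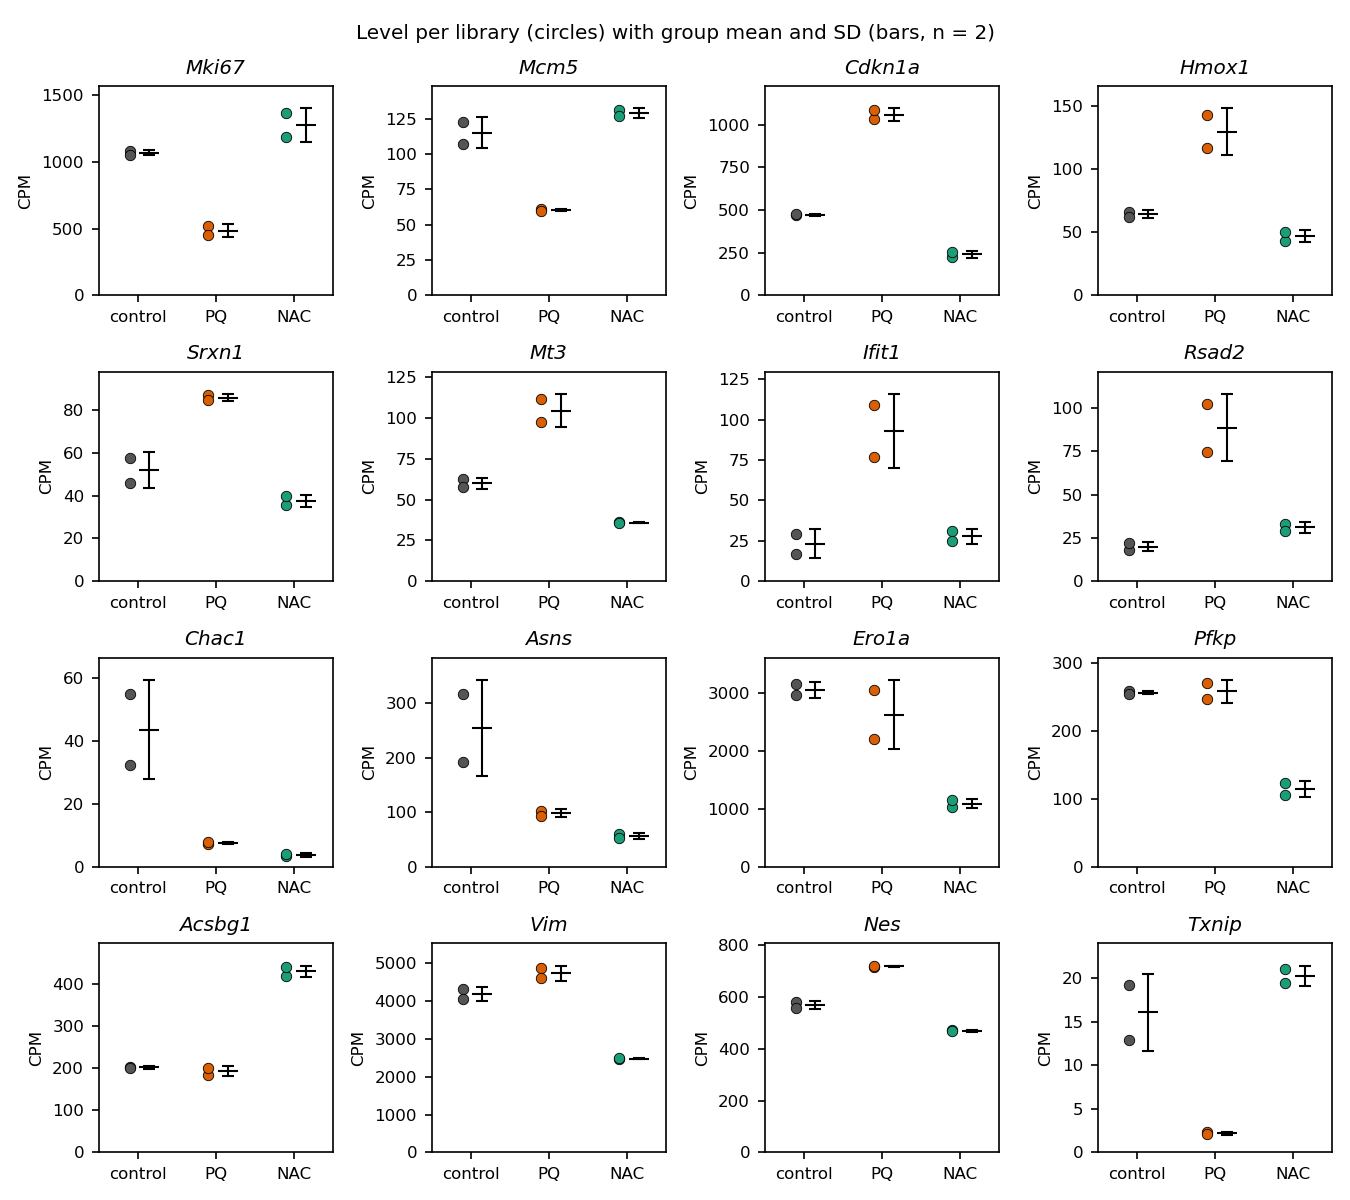
Level of 16 genes in CPM (linear axis from 0) in each of the 6 libraries (circles) with the mean and SD of each group (bars, n = 2). Mki67 and Mcm5 were lowest and Cdkn1a, Hmox1 and Ifit1 highest in the PQ libraries, Ero1a and Pfkp were lowest and Acsbg1 highest in the NAC libraries, and Chac1 and Asns were highest in the control libraries.

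PQ against NAC, the third comparison, sets the treatments against each other and does not use the control means. Most listed cell cycle genes were lower and most p53 targets, hypoxia, interferon-stimulated, NRF2 and cholesterol synthesis genes were higher with PQ than with NAC. Cdkn1a stood at 1058 ± 37.2 CPM with PQ and 239 ± 22.6 CPM with NAC (SD, n = 2), a 4.43-fold difference, and Mki67 at 485 ± 49.7 and 1278 ± 124 CPM, 2.63-fold lower with PQ. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 3926 genes, 1986 higher and 1940 lower with PQ, of which 520 and 287 differed by at least 2-fold (1872 higher and 2046 lower scaled by library size only). The count was 2447 without PQ replicate 2 and 2548 without NAC replicate 1. Of the 24 lists 15 passed camera with its preset correlation, 0 passed with an estimated one (4 had an unadjusted p under 0.05), and 16 passed fry, which did not include the amino acid response, inflammatory, ribosomal protein and lysosome lists that camera called.

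S phase genes were lower with PQ than with NAC in 34 of 38 members and higher in 0 (37 and 1 adjusted over the list alone, camera adjusted p = 7.1e-22, adjusted p = 0.24 with an estimated correlation). Mcm3 and the DNA polymerase Pole were 2.18-fold and 2.34-fold lower. G2 and M phase genes were lower in 36 of 38 and higher in 0 (37 and 0 adjusted over the list alone, camera adjusted p = 4.2e-21, adjusted p = 0.31 with an estimated correlation). Racgap1 (-1.01 ± 0.09) and Hmgb2 (-0.99 ± 0.09) were among them. Of 26 p53 targets 21 were higher and 1 lower (22 and 1 adjusted over the list alone, camera adjusted p = 1.1e-15, adjusted p = 0.09 with an estimated correlation). Ccng1 was 3.55-fold and Trp53inp1 2.54-fold higher. The lower member, Sesn1 (-0.56 ± 0.13), had an edgeR adjusted p of 0.065 without PQ replicate 2. Interferon-stimulated genes were higher in 22 of 25 members and lower in 1 (22 and 1 adjusted over the list alone, camera adjusted p = 5e-10, adjusted p = 0.27 with an estimated correlation). The lower member was Gbp2 (-0.32 ± 0.11), at an edgeR adjusted p of 0.29 without PQ replicate 1, 0.12 without NAC replicate 1 and 0.079 without NAC replicate 2. Rsad2 was 2.86-fold, the interferon regulatory factor Irf7 2.96-fold and Ifit1 3.37-fold higher. Inflammatory genes were higher in 6 of 17 and lower in 1, the complement gene C3 (-0.89 ± 0.19) (6 and 2 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.52 with an estimated correlation). The list call was lost with fry, with no filter and without PQ replicate 2 or NAC replicate 1 (adjusted p up to 0.13 in leave-outs), and 2 members were lower without either control library or NAC replicate 1. Lif, Cxcl10 and Ccl7 were 2.07-fold, 1.67-fold and 2.55-fold higher with PQ. Of 4 microglia genes 1 was higher and 0 lower (2 and 1 adjusted over the list alone), with 0 higher without any 1 PQ or NAC library and 1 lower without either control library or NAC replicate 2.

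Hypoxia and glycolysis genes were higher with PQ than with NAC in 25 of 30 members and lower in 0 (25 and 0 adjusted over the list alone, camera adjusted p = 1.9e-13, adjusted p = 0.35 with an estimated correlation). Pfkp was 2.26-fold, Ero1a 2.41-fold and the glycolytic enzyme Gapdh 1.76-fold higher. Of 27 amino acid response genes 11 were higher with PQ and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.00063, adjusted p = 0.52 with an estimated correlation). Without any 1 of the 4 treated libraries 7 were higher, and without either control library 15 were higher and 1 lower. The mTOR inhibitor gene Ddit4 was 1.97-fold higher. NRF2 targets were higher in 20 of 27 and lower in 2 (21 and 2 adjusted over the list alone, camera adjusted p = 5.1e-09, adjusted p = 0.24 with an estimated correlation). Hmox1, Srxn1 and Akr1b8 were 2.78-fold, 2.28-fold and 2.78-fold higher, and Txnrd1 was 1.36-fold higher. Gclm (0.42 ± 0.10) and Nqo1 (0.88 ± 0.32) were higher, and Blvrb (-0.51 ± 0.14) and Cbr3 (-0.46 ± 0.13) were lower, and leave-outs ended these calls at the edgeR adjusted p given. Gclm was at 0.072 without NAC replicate 2. Nqo1 was at 0.45 without PQ replicate 1 and 0.28 without NAC replicate 2. Blvrb was at 0.13 without PQ replicate 2. Cbr3 was at 0.12 without NAC replicate 2 and 0.079 without PQ replicate 2. Slc7a11 (0.13 ± 0.09, edgeR adjusted p = 0.29) and Ddit3 (0.27 ± 0.25, 0.44) did not pass. Of 23 antioxidant enzymes 4 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.35). Gpx1 was 2.39-fold higher and Txn1 1.61-fold lower. Gpx8 (0.45 ± 0.12), Sod3 (0.47 ± 0.14) and Prdx5 (0.33 ± 0.10) were higher, with calls lost in leave-outs at these edgeR adjusted p. Gpx8 was at 0.14 without PQ replicate 1 and 0.062 without NAC replicate 2. Sod3 was at 0.11 without PQ replicate 2, 0.11 without NAC replicate 1, 0.054 without PQ replicate 1 and 0.051 without NAC replicate 2. Prdx5 was at 0.24 without NAC replicate 1 and 0.19 without PQ replicate 1. Of 11 metallothionein and metal handling genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.33 with an estimated correlation). Mt3 (2.92-fold), Mt1 (2.11-fold), Mt2 (2.03-fold), Tfrc (1.65-fold) and Atp7a (1.72-fold) were higher, and Slc39a10 (-0.59 ± 0.10) and Aco1 (-0.29 ± 0.10) lower. The edgeR adjusted p of Aco1 was 0.21 without PQ replicate 1, 0.12 without NAC replicate 1, 0.1 without NAC replicate 2 and 0.084 without PQ replicate 2. Heat shock proteins were higher in 8 of 15 and lower in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.31 with an estimated correlation). Without PQ replicate 1 the number was 5. Cryab was 4.23-fold higher.

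Astrocyte genes were lower with PQ than with NAC in 12 of 18 members and higher in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.24 with an estimated correlation). Acsbg1 and the bicarbonate transporter Slc4a4 were 2.23-fold and 2.7-fold lower and Gfap 2.44-fold lower, while Gja1 (0.73 ± 0.09), Aldh1l1 (1.66 ± 0.27) and Ndrg2 (0.60 ± 0.15) were higher. Neural stem cell and radial glia genes were higher in 4 and lower in 8 of 20 (5 and 8 adjusted over the list alone, camera adjusted p = 0.35), and 5 were lower without PQ replicate 1 or 2 and 4 without NAC replicate 1. Tnc (2.11-fold), Vim (1.91-fold), Nes (1.53-fold) and Sox9 (1.34-fold) were higher, and Ptprz1 (2.06-fold) was lower. Neurogenic and neuronal genes were higher in 6 and lower in 4 of 19 (7 and 5 adjusted over the list alone, camera adjusted p = 0.56). Celf4, Nefm and Nefl were 3.78-fold, 2.82-fold and 2.89-fold higher with PQ, and Map2 (1.82-fold), Gap43 (2.37-fold) and Robo2 (1.47-fold) were lower. Hes1 (-0.39 ± 0.11), Olig2 (-0.27 ± 0.09) and Sirt1 (-0.64 ± 0.15) were lower, and Sox2 (-0.04 ± 0.10, edgeR adjusted p = 0.76) and Tubb3 (0.63 ± 0.56, 0.43) did not pass. Leave-outs ended 5 calls, at these edgeR adjusted p. Ndrg2 was at 0.069 without NAC replicate 1 and 0.061 without PQ replicate 1. Sox9 was at 0.065 without NAC replicate 1. Hes1 was at 0.22 without PQ replicate 2 and 0.1 without NAC replicate 1. Olig2 was at 0.31 without PQ replicate 1, 0.12 without NAC replicate 2 and 0.11 without NAC replicate 1. Sirt1 was at 0.06 without NAC replicate 1 and 0.056 without PQ replicate 2.

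Some oligodendrocyte lineage, fibroblast and pericyte, and sirtuin and NAD genes changed in each of the 3 comparisons. Oligodendrocyte lineage genes were 1 higher and 1 lower of 11 (1 and 1 adjusted over the list alone, camera adjusted p = 0.9) with PQ. Myrf (0.96 ± 0.22) was higher and Nkx2-2 (-0.52 ± 0.12) lower (2 lower without PQ replicate 1). NAC gave 3 higher and 0 lower of 11 (3 and 0 adjusted over the list alone, camera adjusted p = 0.2), among them Pdgfra (0.40 ± 0.11) and Olig1 (0.41 ± 0.12), and 0 higher without control replicate 2 or NAC replicate 2. PQ against NAC gave 1 higher and 4 lower of 11 (1 and 5 adjusted over the list alone, camera adjusted p = 0.25), 2 lower without NAC replicate 2. Myrf (1.44 ± 0.23) was higher and Nkx2-2 (-0.58 ± 0.12), Pdgfra (-0.49 ± 0.11), Olig2 (-0.27 ± 0.09) and Ugt8a (-0.54 ± 0.20) lower. Fibroblast and pericyte genes were 4 higher and 2 lower of 10 (5 and 2 adjusted over the list alone, camera adjusted p = 0.2) with PQ. Col6a1 (0.84 ± 0.12), Acta2 (2.83 ± 0.69), Dcn (2.32 ± 0.71) and Col6a2 (0.99 ± 0.33) were higher and Col3a1 (-0.91 ± 0.14) and Fn1 (-0.35 ± 0.10) lower. With NAC they were 1 higher and 3 lower of 10 (1 and 4 adjusted over the list alone, camera adjusted p = 0.28) (median 0.02, mean 0.24, downward test). Acta2 (2.36 ± 0.73) was higher and Fn1 (-0.98 ± 0.10), Col6a1 (-0.91 ± 0.14) and Col6a2 (-1.33 ± 0.43) lower. PQ over NAC gave 3 higher and 1 lower of 10 (3 and 1 adjusted over the list alone, camera adjusted p = 0.066). Col6a1 (1.75 ± 0.13), Fn1 (0.63 ± 0.10) and Col6a2 (2.32 ± 0.38) were higher and Col3a1 (-0.54 ± 0.14) lower. Without control replicate 2 the log2 fold changes were 3.77 for Acta2 and 3.82 for Dcn with PQ and 3.30 for Acta2 with NAC, and without control replicate 1 that of Dcn with PQ was 1.58. Dcn was below the count filter without PQ replicate 2 or NAC replicate 2. Sirtuin and NAD genes were 1 higher and 2 lower of 15 (1 and 2 adjusted over the list alone, camera adjusted p = 0.9) with PQ. The NAD hydrolase Cd38 (0.95 ± 0.14) was higher and Parp1 (-0.41 ± 0.11) and Parp2 (-0.54 ± 0.14) lower (median -0.03, mean 0.03, downward test). NAC gave 1 higher and 1 lower of 15 (1 and 1 adjusted over the list alone, camera adjusted p = 0.73), Sirt1 (0.47 ± 0.14) higher (2 higher without control replicate 1) and Nampt (-0.61 ± 0.10) lower. Between the treatments they were 4 higher and 3 lower of 15 (4 and 3 adjusted over the list alone, camera adjusted p = 0.65). Nampt (0.52 ± 0.10), Cd38 (0.54 ± 0.14), Nmnat1 (0.61 ± 0.18) and Nmnat2 (0.44 ± 0.14) were higher and Parp1 (-0.61 ± 0.11), Parp2 (-0.63 ± 0.14) and Sirt1 (-0.64 ± 0.15) lower. Endothelial genes were 1 higher and 0 lower of 2 (1 and 0 adjusted over the list alone) with PQ, Flt1 (0.45 ± 0.11). They were 0 higher and 0 lower of 2 (0 and 1 adjusted over the list alone) with NAC and 1 higher and 0 lower of 2 (2 and 0 adjusted over the list alone) for PQ against NAC, Egfl7 (0.84 ± 0.28). Leave-outs ended 9 calls for PQ against control, at these edgeR adjusted p. Myrf was at 0.16 without PQ replicate 2. Nkx2-2 was at 0.091 without PQ replicate 2 and 0.057 without control replicate 2. Acta2 was at 0.14 without PQ replicate 2 and 0.051 without control replicate 1. Dcn was at 0.15 without control replicate 1. Col6a2 was at 0.29 without PQ replicate 2, 0.2 without control replicate 2, 0.068 without PQ replicate 1, 0.054 without control replicate 1 and 0.05 without NAC replicate 1. Fn1 was at 0.28 without PQ replicate 2 and 0.12 without control replicate 1. Parp1 was at 0.17 without control replicate 1, 0.1 without PQ replicate 2 and 0.081 without PQ replicate 1. Parp2 was at 0.14 without PQ replicate 2 and 0.064 without control replicate 2. Flt1 was at 0.12 without PQ replicate 1. They ended 5 for NAC against control. Pdgfra was at 0.16 without NAC replicate 2 and 0.068 without control replicate 2. Olig1 was at 0.23 without NAC replicate 2 and 0.18 without control replicate 2. Acta2 was at 0.16 without control replicate 1, 0.15 without NAC replicate 2 and 0.059 without NAC replicate 1. Col6a2 was at 0.19 without control replicate 1, 0.17 without NAC replicate 1, 0.13 without NAC replicate 2 and 0.053 without PQ replicate 2. Sirt1 was at 0.28 without NAC replicate 1 and 0.16 without control replicate 1. They ended 8 for PQ against NAC. Olig2 was at 0.31 without PQ replicate 1, 0.12 without NAC replicate 2 and 0.11 without NAC replicate 1. Ugt8a was at 0.51 without PQ replicate 2, 0.2 without NAC replicate 1 and 0.066 without NAC replicate 2. Col3a1 was at 0.11 without NAC replicate 1 and 0.06 without PQ replicate 2. Cd38 was at 0.096 without NAC replicate 1. Nmnat1 was at 0.084 without NAC replicate 2, 0.077 without PQ replicate 1, 0.059 without PQ replicate 2 and 0.053 without NAC replicate 1. Nmnat2 was at 0.11 without PQ replicate 2, 0.088 without NAC replicate 1, 0.083 without NAC replicate 2 and 0.07 without PQ replicate 1. Sirt1 was at 0.06 without NAC replicate 1 and 0.056 without PQ replicate 2. Egfl7 was at 0.15 without PQ replicate 1, 0.12 without NAC replicate 1, 0.089 without NAC replicate 2 and 0.062 without PQ replicate 2.

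The largest differences between the treatments at 5 CPM or more fell largely outside these lists. Higher with PQ were Adssl1 (8.41-fold), the transcription elongation factor Tcea3 (6.7-fold), Ripor2 (5.53-fold), the G protein signalling regulator Rgs8 (5.42-fold), the guanine deaminase Gda (5.14-fold), Ahnak (5-fold), Tcam1 (4.87-fold), Tinagl1 (4.77-fold) and Lipg (4.67-fold), with edgeR adjusted p of 4.9e-06 or less. Lower with PQ were Ankrd34c (14-fold), Txnip (9.22-fold), Prr18 (8.22-fold), Galnt16 (6.27-fold), the phosphodiesterase Pde7b (6.21-fold), Brinp2 (5.22-fold), Igsf10 (5-fold), Tmem100 (4.96-fold), the imprinted gene Peg10 (4.93-fold) and the adhesion molecule Cntn1 (4.9-fold), with edgeR adjusted p of 5.3e-06 or less.

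Both treatments were set against the same 2 control libraries, and across 12813 genes their log2 fold changes correlated with a Pearson r of 0.302 and a Spearman rho of 0.184. Genes are not independent replicates. In 50 simulations of unchanged groups against shared controls r averaged 0.509 and reached 0.539, because shared control libraries alone correlate such fold changes. The observed covariance was 0.0708 and the simulated mean covariance 0.0212, a difference of 0.0497. Over the 10787 genes with a mean of at least 5 CPM the observed covariance was 0.0459. Each treatment set against a different single control library gave r = 0.094 and 0.061, and leaving out control replicate 1 or 2 gave 0.437 or 0.44. With these separate controls the covariance of differences in log2 CPM was 0.0194 and 0.013. The difference of 0.0497 is therefore not shown to be a response that the treatments share. Of the called genes 259 rose with both treatments and 214 fell with both, where lists drawn independently would share 100.5 and 104.3. The opposite directions held 157 genes that rose with PQ and fell with NAC and 75 that fell with PQ and rose with NAC, against 107.6 and 97.5 from independent lists. The simulations of unchanged groups gave a mean of 0.08 genes called higher with both, 0.18 lower with both and 0 in opposite directions. They hold no changed genes, so they do not show how far shared controls add to the overlap of changed ones. With only 2 controls no split keeps 2 libraries on each side, so this was not tested. Of 27 amino acid response genes 19 fell with PQ and 24 with NAC, while hypoxia and glycolysis genes fell with NAC in 28 of 30 members and with PQ in 6.

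**Figure D3:**
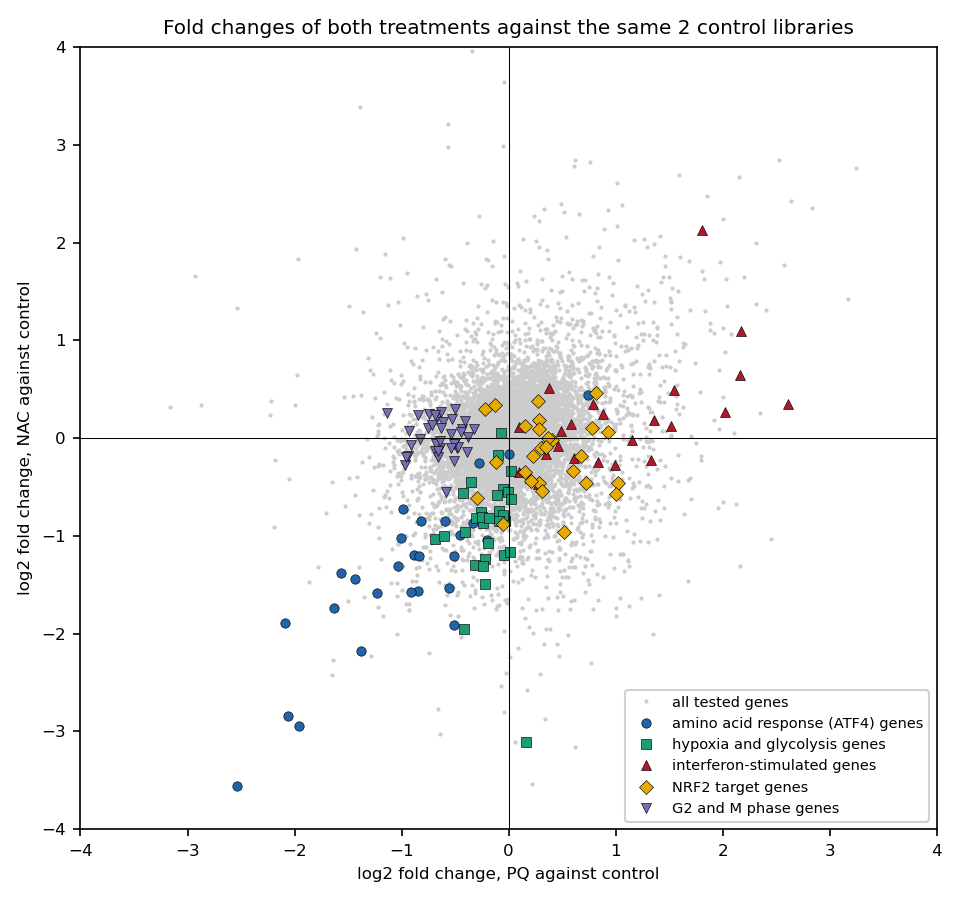
Log2 fold change against control with PQ (horizontal) and with NAC (vertical) for the tested genes (grey, 14 genes beyond 4 on either axis not drawn) and for the members of 5 gene lists (coloured symbols). Most amino acid response genes lie in the lower left, most hypoxia and glycolysis genes below 0 on the NAC axis and the G2 and M phase genes to the left of 0 on the PQ axis.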

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

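The counts of called genes kept within 1.5 times of the values above under other tools, scalings, filters and units, with 1578 to 2617 genes for PQ against control, and moved further only when a library was left out. A similar count does not mean the same genes. Of the 2289 calls for PQ against control, 67.9% stayed called in the same direction with DESeq2. The share was 68.5% with limma on log2(FPKM + 1) and 99.5% with RLE scaling. DESeq2 called fewer genes, and 1555 of its 1578 were among the 2289. Leave-outs gave 846 to 2193 genes for PQ against control, 1332 to 2180 for NAC against control and 2447 to 4433 for PQ against NAC. The lone library of a group has no spread of its own. For PQ against NAC the count rose from 3926 when a control library was left out, and it was 4441 with only the 2 groups compared. Control libraries enter that comparison only through the shared spread, the scaling and the filter. Which of these raised the count, and the reasons for the other moves, were not tested. The number of lists called was 14, 11 and 15, and 0, 0 and 0 with a correlation estimated from the residuals, where 4, 1 and 4 had an unadjusted p under 0.05. That estimate rests on 3 residual degrees of freedom. With fry 11, 1 and 16 lists passed, of which 9, 1 and 11 were among those called by camera, and leave-outs gave 12 to 14, 9 to 11 and 12 to 16. No called list changed direction.

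The correlation of the PQ and NAC fold changes, 0.302, became 0.094 and 0.061 when each treatment had its own control library, and lay between 0.207 and 0.44 over the leave-outs. Separate controls remove the shared chance values by construction. Among the named genes no called gene changed direction under any alternative. Gfap, not called with PQ, was at 0.15 without control replicate 1 and 0.04 without PQ replicate 2, in a range of -0.23 to 0.15. Nqo1, not called with NAC, was at -0.17 without control replicate 2 and -0.29 without NAC replicate 1, in a range of -0.29 to 0.35. The cause was not tested.

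A replicate block by run of library numbers gave 1842 genes for PQ against control, 1901 for NAC against control and 3485 for PQ against NAC. Deviations of libraries in the same run correlated at -0.068 (control and PQ), -0.112 (control and NAC) and 0.112 (PQ and NAC). These weak values show no strong pairing over all genes. With 1 deviation per gene and group they cannot exclude a batch in part of the genes or groups. In data simulated at 1 setting, with these depths and spreads and 2 libraries per group, 63.64% of 1.5-fold changes with PQ against control were found.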

Other observations

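Some lysosome, cholesterol synthesis, ribosomal protein and immediate early genes were called in each comparison. Over all tested genes the share called was 17.9% for PQ against control, 17.9% for NAC against control and 30.6% for PQ against NAC. Lysosome and autophagy genes with PQ against control were 14 higher and 0 lower of 24 (16 and 0 adjusted over the list alone, camera adjusted p = 8.3e-09, adjusted p = 0.19 with an estimated correlation), and 8 rose without PQ replicate 1 and 5 without PQ replicate 2. The protease gene Ctsd rose 1.77-fold and Sqstm1 1.76-fold. With NAC they were 5 higher and 0 lower of 24 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.46 with an estimated correlation), 3 higher without NAC replicate 2. Gpnmb (1.09 ± 0.17), Map1lc3b (0.59 ± 0.10), Sqstm1 (0.46 ± 0.10), Gabarapl1 (0.41 ± 0.11) and Lamp1 (0.29 ± 0.09) rose, and leave-outs ended 2 calls. Gabarapl1 was at 0.11 without NAC replicate 2 and 0.077 without control replicate 2. Lamp1 was at 0.19 without control replicate 1, 0.15 without NAC replicate 1 and 0.094 without NAC replicate 2. For PQ against NAC they were 9 higher and 1 lower of 24 (10 and 1 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.47 with an estimated correlation). Ctsd was 1.56-fold and Ctsb 1.57-fold higher and Map1lc3b (-0.28 ± 0.10) lower, the last at an edgeR adjusted p of 0.18 without NAC replicate 1, 0.15 without PQ replicate 1, 0.14 without PQ replicate 2 and 0.072 without NAC replicate 2. In leave-outs 5 were higher without PQ replicate 2 and 4 without NAC replicate 1. The list call was lost without control replicate 2, PQ replicate 2 or NAC replicate 1 (up to 0.21) and under the block. Cholesterol synthesis genes with PQ were 8 higher and 0 lower of 24 (8 and 0 adjusted over the list alone, camera adjusted p = 8.1e-05, adjusted p = 0.43 with an estimated correlation), with Hsd17b7 1.6-fold and Nsdhl 1.35-fold higher. In leave-outs 13 rose without control replicate 1, 5 without control replicate 2 or PQ replicate 2 and 2 without PQ replicate 1. Without control replicate 2 the list call was lost (0.057). With NAC they were 0 higher and 2 lower of 24 (0 and 2 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.64 with an estimated correlation). Fdps (-0.44 ± 0.10) and Pmvk (-0.45 ± 0.11) fell, and leave-outs ended both calls. Fdps was at 0.075 without NAC replicate 2 and 0.064 without control replicate 1. Pmvk was at 0.062 without control replicate 1. Without control replicate 2 there were 6 lower members. The list call was lost with library size only and without control replicate 1, NAC replicate 1 or NAC replicate 2 (up to 0.79). Between PQ and NAC they were 16 higher and 0 lower of 24 (18 and 0 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.43 with an estimated correlation), with Nsdhl 1.63-fold higher. In leave-outs 9 were higher without PQ replicate 1 and 8 without NAC replicate 1. Ribosomal protein genes were 0 higher and 16 lower of 58 (1 and 27 adjusted over the list alone, camera adjusted p = 9.1e-09, adjusted p = 0.22 with an estimated correlation) with PQ. In leave-outs 7 fell without control replicate 2, 3 without PQ replicate 1 and 1 without PQ replicate 2. They were 0 higher and 4 lower of 58 (0 and 0 adjusted over the list alone, camera adjusted p = 0.081) with NAC. Among these were Rps3 (-0.35 ± 0.09), Rps14 (-0.33 ± 0.09) and Rps2 (-0.29 ± 0.09), and leave-outs ended each of their calls, with 2 of the 58 lower without control replicate 1, 1 without control replicate 2 and 0 without NAC replicate 1 or 2. Rps3 was at 0.12 without control replicate 2, 0.11 without NAC replicate 1 and 0.052 without NAC replicate 2. Rps14 was at 0.12 without control replicate 2, 0.12 without NAC replicate 1 and 0.072 without NAC replicate 2. Rps2 was at 0.25 without NAC replicate 1, 0.11 without control replicate 1, 0.054 without control replicate 2 and 0.052 without NAC replicate 2. Set against NAC, PQ gave 0 higher and 8 lower of 58 (0 and 2 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.44 with an estimated correlation). In leave-outs 2 were lower without PQ replicate 1 or NAC replicate 2 and 1 without PQ replicate 2, where the list call was lost (0.089). Immediate early genes were 6 higher and 1 lower of 21 (10 and 2 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.4 with an estimated correlation) with PQ, 2 higher without PQ replicate 2. Fosl1 was 1.87-fold higher and Egr1 (-0.59 ± 0.10) lower. They were 7 higher and 2 lower of 21 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.46 with an estimated correlation) with NAC. Zfp36 was 2.24-fold higher and Fosl1 (-0.46 ± 0.11) and Klf4 (-0.49 ± 0.13) lower, the last 2 with calls ended by leave-outs. Fosl1 was at 0.1 without NAC replicate 1 and 0.066 without control replicate 1. Klf4 was at 0.15 without control replicate 2 and 0.11 without NAC replicate 1. In PQ against NAC they were 6 higher and 7 lower of 21 (6 and 9 adjusted over the list alone, camera adjusted p = 0.42). Fosl1 was 2.57-fold higher and Egr1 2.2-fold lower, with 4 lower without PQ replicate 1 or NAC replicate 2.

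Some Notch pathway, endoplasmic reticulum chaperone and respiratory chain genes changed in each comparison. Notch pathway genes were 2 higher and 2 lower of 15 (2 and 2 adjusted over the list alone, camera adjusted p = 0.54) with PQ. Lfng (-0.71 ± 0.10) and Nrarp (-0.91 ± 0.24) were lower and Notch3 (0.44 ± 0.14) and Dtx4 (0.31 ± 0.10) higher, with a median of 0.03, a mean of -0.12 and a downward test. With NAC they were 4 higher and 2 lower of 15 (5 and 3 adjusted over the list alone, camera adjusted p = 0.44). Dll1 (2.02 ± 0.22), Dll4 (1.93 ± 0.41), Hey1 (0.64 ± 0.16) and Nrarp (0.79 ± 0.20) rose and Rbpj (-0.55 ± 0.10) and Hes6 (-0.50 ± 0.15) fell. In leave-outs 1 rose without NAC replicate 2 and 3 without control replicate 2 or NAC replicate 1, and Dll4 was below the count filter without either NAC library. Comparing PQ with NAC, they were 4 higher and 6 lower of 15 (4 and 6 adjusted over the list alone, camera adjusted p = 0.35). Rbpj (0.57 ± 0.10), Jag2 (2.53 ± 0.58), Notch3 (0.62 ± 0.15) and Hes6 (0.54 ± 0.15) were higher, and Jag2 was at 3.29 without NAC replicate 2. Endoplasmic reticulum chaperones were 2 higher and 1 lower of 20 (2 and 1 adjusted over the list alone, camera adjusted p = 0.2) with PQ. Hspa5 (0.37 ± 0.09) and Calr (0.36 ± 0.09) were higher and Herpud1 (-0.53 ± 0.14) was lower. With NAC they were 4 higher and 1 lower of 20 (4 and 1 adjusted over the list alone, camera adjusted p = 0.21). Hspa5 (0.33 ± 0.09), Dnajc3 (0.41 ± 0.11), Calr (0.32 ± 0.09) and Dnajb9 (0.42 ± 0.14) were higher and Herpud1 (-0.85 ± 0.15) was lower. With PQ against NAC they were 0 higher and 1 lower of 20 (0 and 1 adjusted over the list alone, camera adjusted p = 0.96), with a median of 0.01, a mean of -0.01 and an upward test, and Dnajc3 (-0.45 ± 0.11) was the member. Respiratory chain genes were 3 higher and 0 lower of 58 (0 and 0 adjusted over the list alone, camera adjusted p = 0.54) with PQ, and 6 rose without control replicate 2. Those 3 were Cox6b1 (0.36 ± 0.11), Sdhd (0.33 ± 0.10) and Atp5l (0.33 ± 0.10). NAC gave 0 higher and 3 lower of 58 (0 and 2 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.46 with an estimated correlation), 9 lower without control replicate 1. They were Uqcrq (-0.71 ± 0.11), Sdhb (-0.44 ± 0.09) and Cox7b (-0.33 ± 0.09), and the list call was lost without control replicate 2 (0.11). In the PQ and NAC contrast they were 13 higher and 0 lower of 58 (12 and 0 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.33 with an estimated correlation), 8 without PQ replicate 1, PQ replicate 2 or NAC replicate 1. Cox7b was 1.45-fold higher. Leave-outs ended calls at these edgeR adjusted p, first for PQ against control. Nrarp was at 0.22 without PQ replicate 2. Notch3 was at 0.26 without PQ replicate 2, 0.25 without control replicate 2 and 0.069 without PQ replicate 1. Dtx4 was at 0.42 without PQ replicate 2, 0.12 without control replicate 2, 0.065 without control replicate 1, 0.054 without NAC replicate 1 and 0.053 without NAC replicate 2. Hspa5 was at 0.086 without PQ replicate 1. Herpud1 was at 0.19 without PQ replicate 2 and 0.16 without control replicate 2. Calr was at 0.089 without PQ replicate 2. Cox6b1 was at 0.21 without PQ replicate 2 and 0.11 without control replicate 2. Sdhd was at 0.18 without PQ replicate 1, 0.16 without control replicate 2 and 0.087 without PQ replicate 2. Atp5l was at 0.18 without PQ replicate 1, 0.1 without control replicate 1 and 0.096 without PQ replicate 2. For NAC against control there were 8. Hey1 was at 0.083 without control replicate 2 and 0.062 without NAC replicate 2. Nrarp was at 0.051 without NAC replicate 2. Hes6 was at 0.29 without NAC replicate 1 and 0.18 without control replicate 1. Hspa5 was at 0.13 without NAC replicate 1 and 0.057 without control replicate 2. Dnajc3 was at 0.2 without NAC replicate 1. Calr was at 0.2 without NAC replicate 1 and 0.093 without control replicate 2. Dnajb9 was at 0.47 without NAC replicate 1 and 0.21 without control replicate 1. Cox7b was at 0.15 without NAC replicate 1, 0.13 without control replicate 2 and 0.065 without NAC replicate 2. For PQ against NAC there were 3. Notch3 was at 0.087 without NAC replicate 1. Hes6 was at 0.17 without NAC replicate 1 and 0.077 without PQ replicate 2. Dnajc3 was at 0.093 without NAC replicate 1 and 0.089 without PQ replicate 2.

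All tests of explanations below were chosen after the result they address was seen. Amino acid response genes were lower with both treatments than in control, and high values in control replicate 2 could account for that, since its median over the list was 0.97 above the gene means against 0.4 in control replicate 1, -0.1 and -0.23 with PQ and -0.53 and -0.54 with NAC. Without control replicate 2, 16 of the 19 members called lower with PQ and 23 of the 24 called lower with NAC were still called, with medians of -0.64 and -0.9 in place of -0.89 and -1.31. A scaling factor moves all genes of a library alike and keeps their order, but 22 and 24 of the 27 members lay in the lowest 10% of the fold changes of all tested genes with PQ and with NAC. These values speak against that library alone and against scaling as the whole cause. A state of the control cultures remains open. Between PQ and NAC 23 of 27 members were higher with PQ and 11 were called, 7 without any 1 treated library and 16 (15 higher, 1 lower) without either control library, so the call depends on the library left out.

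Interferon-stimulated and inflammatory genes rose with PQ, and immune cells in the cultures could carry them. All 17 listed microglia and blood cell genes found in the tables summed to 81.9 and 80.3 CPM with PQ and 63.1 and 61.5 in control. That is a rise of at most 19.6 CPM over the control mean, against a summed rise of 1536.7 CPM over 42 interferon-stimulated and inflammatory genes, where such cells would bring their own abundant transcripts too. These sums speak against such cells as the main source, though the ratio of these transcripts within such cells was not measured. A small number of them stays possible, since all 4 microglia genes that could be tested had a higher estimate with PQ (median log2 fold change 0.51). The 13 listed genes below the filter summed to 1.77 and 2.07 CPM with PQ and 1.01 and 0.31 in control. Low values in control are another possibility, but 22 of 25 interferon-stimulated genes were also higher in PQ than in NAC. For inflammatory genes 6 of 17 were, which leaves that question open. The biological alternative is a response to PQ within the neural cells, which was not tested apart from these checks.

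Fam177a (Entrez gene 73385, chromosome 12, 55124435 to 55142104 of GRCm38) had expected counts of 0 and 0 in control, 178.3 and 199.8 with PQ and 0 and 133.4 with NAC. Its near-copy Fam177a2 had 252.2 and 280, 178.3 and 200, and 332 and 133.4. The summed level of both copies was higher with PQ by 0.46 on the log2 scale, so the appearance of Fam177a is likely a division of shared reads between the copies. No biological explanation was tested.

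If redox potential set NRF2 activity on a scale, its targets could be ordered PQ above control above NAC. That order held for 14 of 27 members by mean CPM. It held for 21.1% of all tested genes by mean log2 CPM, so the 2 shares use unlike measures. The order also held for 15 of 26 p53 targets, 16 of 24 cholesterol synthesis genes and 6 of 11 metallothionein and metal handling genes. It is therefore not specific to NRF2, and the shared control enters both steps.

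Peg10 was among the genes with the largest decrease in PQ against NAC, and imprinted genes could move as a group. Of 20 tested imprinted genes 7 were lower and 3 higher (camera p = 0.048, 0.14 with an estimated correlation, fry p = 0.004), with Peg10 (-2.30 ± 0.12), Mest (-1.80 ± 0.10), Peg3 (-1.31 ± 0.19) and Peg12 (-1.06 ± 0.13) lower. The 3 higher were Inpp5f (0.45 ± 0.10), Igf2r (0.64 ± 0.09) and Blcap (0.58 ± 0.14, edgeR adjusted p 0.081 without PQ replicate 2), which speaks against a move of the whole group in that comparison. With NAC against control 6 were higher and 0 lower (camera p = 0.0097, 0.078 with an estimated correlation, fry p = 0.0096), and with PQ against control 3 were higher and 5 lower (camera p = 0.57). With NAC 9 of the 20 estimates lay below 0, with a median log2 fold change of 0.08, so the calls had 1 direction but a rise of the whole group is not shown. Of all tested genes 30.6% were called in PQ against NAC and 17.9% in NAC against control. Peg10, which prompted the list, is in the tested set, so these camera and fry p are partly set by it. No value without Peg10 was computed. These p are not adjusted over the comparisons, and no technical explanation was tested.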
